A study of Homo sapiens with 3 samples.

How the data were processed

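Total RNA of MDA-MB-231 cells was labelled with biotin and hybridised to 1-colour Illumina bead arrays, per the labels' protocols. Each of 3 conditions had 1 array: untreated, ADI-PEG20 for 48 h, and ADI-PEG20 for 24 h then L-arginine for 24 h. Samples were grouped by their titles and treatment labels.

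The authors deposited a table of probe intensity on a linear scale for 47231 probes. GenomeStudio is named in the submitters' processing notes, without a version, and the normalization and background steps are not given in the sources used here. The values themselves showed equal minima of 106, equal maxima of 28717 and medians of 149.35, 149.35 and 149.34 for the untreated, ADI-PEG20 and arginine arrays, a shared distribution such as quantile normalization gives. Scale was read from the values as linear and not centred. The exact normalization stays unknown, and a change in total RNA per cell could not be seen after it. A 1-colour array has no ratio direction.

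A second deposited table, of values before normalization with detection p-values, was not used. Its 6 columns of per-sample values carry names that match no single sample label. The design fixed before the data were examined had planned limma's neqc on that table, with a detection p as the filter. In its place the deposited intensity was corrected by normexp, which models each value as exponential signal plus normal background. The background mean was the mode of the intensities, 136.92, the background SD was that of the lower side of the mode, 8.76, and the exponential mean was 425. These settings were chosen from the intensity distribution, after the table was seen. An offset of 16 was added and log2 taken, with no further normalization between arrays. A probe was above background where its intensity exceeded the mode by 3 background SDs, a limit of 163.187, which 38.1% of probes did on each array. The number of arrays limits the precision, and intensities near that limit are compressed by the offset.

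Of the probes, 30121 had a gene in the platform annotation and 17110 had none listed there. A single gene was given for 30113 probes and several for 8, which were not named. Symbols were taken through the gene identifier for 30074 probes and through the accession for 18, and 21 kept the platform's symbol. The symbol of 11 probes was updated. A gene was represented by its probe with the highest mean over the arrays. It entered a comparison if that probe was above background on at least 1 of the 2 arrays. Among the probes with no gene listed, 106 were at least 2-fold higher and 79 lower under ADI-PEG20, of 4608 above background. No genome coordinates are given, since the sources used here name no build.

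Each comparison was a difference of log2 values, counted at a threshold of 2-fold. Counts use the measured difference of every gene that entered, and are given beside counts with the bounds described next. With 1 array per condition there was no test between groups. For a gene above background on 1 of the 2 arrays the fold is a bound, written as at least. It sets the bright value against the lowest value above background on the dim array, or the dim probe's own value if higher. The error between probes was the SD of the difference between the 2 brightest probes' log2 differences, divided by the square root of 2. It holds real differences between transcripts too.

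There were 41 gene lists, written before the data were examined. A list's median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these arrays. Named genes were chosen by a rule fixed before the data were examined. It took the 12 genes with the largest difference in each direction among those above background on both arrays, the 3 with the largest bound, and of each list the 3 members with the largest difference. It also took ASS1 and the list of arginine and polyamine metabolism. Unnamed loci and open reading frame names were passed over. Other list members named in the text, and the relation of JUNB, CREB3 and TSPYL2 to both treated samples, were chosen after their values were seen.

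Simulated unchanged arrays of equal noise that share a control were drawn 100 times. Simulated arrays with known differences were passed through the same steps. The first comparison held 11449 genes. There 36.7% of 49 genes made 2-fold higher and 32.6% of 46 made 2-fold lower passed the 2-fold threshold, with median estimates of 0.87 and -0.89. Of 50 genes made 4-fold higher and 48 made 4-fold lower, 98.0% and 95.8% passed. Among genes left unchanged, 46 passed upward and 48 downward in the first comparison, and 48 and 45 in the second. Noise in this simulation was set from the probe error and the background SD of the same arrays, so it is not an independent estimate of noise between cultures. For the simulations the probe error was taken from the median absolute deviation in place of the SD, which gave a smaller noise of 0.1303 per array. Of 100 random lists of 30 genes shifted by 0.3, all 100 lay above the 97.5th percentile, and 7 of 100 unshifted lists lay outside the central 95%.

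Alternatives changed 1 step at a time: no background correction, an offset of 50, other background limits, no limit, both arrays above the limit, the mean over probes, bounds for dim values, thresholds of 1.5-fold and 3-fold, and reading the return after arginine on a second probe. Confidence intervals over genes used 2000 bootstrap draws. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.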

Results

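Gene expression was measured in MDA-MB-231 cells, a human breast carcinoma line of basal, mesenchymal-like type, with 1-colour bead arrays. The series describes the line as deficient in ASS1, argininosuccinate synthase, which makes the arginine precursor argininosuccinate from citrulline and aspartate. ADI-PEG20 is a pegylated arginine deiminase, an enzyme that degrades extracellular arginine to citrulline and ammonia. There were 3 samples with 1 array each: untreated cells kept for 48 h, cells given ADI-PEG20 at 0.3 µg/ml for 48 h, and cells given ADI-PEG20 for 24 h followed by L-arginine at 420 µg/ml for 24 h. For the last sample the label gives the ADI-PEG20 dose as 0.3 with a unit that is cut short. No condition was replicated, so no difference below could be set against a spread between samples, and all differences compare these arrays and not the conditions as such. Of 20039 genes with a named probe, 11448 were above background on at least 1 array and 9847 on all 3. Differences are given on the log2 scale of background-corrected intensity, with the first-named sample minus the second.

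The first comparison asked which transcripts differed in cells given ADI-PEG20 for 48 h from those in untreated cells. Transcripts of several enzymes of amino acid synthesis and of most amino acid transporters were higher under ADI-PEG20, and transcripts of cell division were lower. ASNS, asparagine synthetase, had the highest difference among genes above background on both arrays, 4.14 or 17.7-fold, from an intensity of 664 to 9722. Another probe of ASNS gave 3.38. CTH, cystathionine gamma-lyase of cysteine synthesis, differed by 3.05, and PSAT1 and PHGDH, enzymes of serine synthesis, differed by 2.79 and 2.61. For PHGDH the intensity was 189 in untreated cells, near the background limit, and 532 under ADI-PEG20. The size of its difference thus depends on the background correction. The centromeric histone gene CENPA differed by -1.99 (-1.41 on another probe) and the mitotic kinesin gene KIF20A by -1.93. Across 11135 genes above background on either array, the measured difference was 2-fold or more upward in 195 and downward in 235. In simulated arrays with noise set from the probe error and background of these arrays, 46 unchanged genes passed upward and 48 downward. With genes below background on 1 array held at their bound, 127 were at least 2-fold higher and 176 at least 2-fold lower. A second probe of the same gene set the error of a difference at 0.22 (SD over 2541 genes with 2 probes), which covers probes and not cultures. Of 67 genes past 2-fold on the brighter probe, 65 had the same sign on the other and 38 were past 2-fold there too.

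Targets of ATF4, the transcription factor of the amino acid response, had a median difference of 1.19 over 35 genes above background. In this list 34 genes were higher, 23 of them with a measured difference of 2-fold or more, and the median lay above all 10000 random lists matched on expression. With the members below background on 1 array set at their bound, the median was 1.11 and 22 were at least 2-fold higher. ATF4 itself differed by 1.02, ATF3 by 1.56 and TRIB3, a pseudokinase that restrains ATF4, by 1.84. CHAC1, a glutathione-degrading enzyme, was at least 4.73-fold higher. The exception was ATF5, at -0.59, and DDIT3, which encodes the stress factor CHOP, was at 0.23. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had a median of 0.73 over 18 genes, with 7 at least 2-fold higher, above all random lists. The highest were YARS1 at 1.497, WARS1 at 1.44 and MARS1 at 1.43, while HARS1 was at -0.89, the arginyl-tRNA synthetase gene RARS1 at 0.13 and 4 members in all were lower. Their mitochondrial counterparts had a median of 0.17 over 16 genes, at the 93.9th percentile. Serine, glycine and one-carbon genes had a median of 0.61 over 15 genes, 10 of them higher and 5 lower, with 5 at least 2-fold higher. CTH, PSAT1 and PHGDH led, of which CTH and PSAT1 also belong to the ATF4 list. The lists thus share members and are not separate evidence. With members not above background on either array included, that median was 0.27. Amino acid transporters had a median of 0.56 over 19 genes, with 5 at least 2-fold higher once members below background on 1 array were held at their bound. SLC6A9, a glycine transporter, differed by 2.36 from an untreated intensity of 170, near the background limit. SLC7A11, the cystine-glutamate exchanger, was at least 2.22-fold higher.

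Genes of arginine and polyamine metabolism had a median of 0.14 over 25 genes, at the 94.8th percentile, so the list as a whole lay within the range of random lists. ASS1 had an intensity of 522 in untreated cells, 1042 under ADI-PEG20 and 576 after arginine, all above the background limit of 163. The untreated value lay above 76.3% of all genes with a probe. Of those 20039 genes only 10590 were above background in untreated cells, so its place among expressed genes was lower. The series describes the line as deficient in ASS1, and these arrays measured RNA and not the protein or its activity. The difference of ASS1 under ADI-PEG20 was 1.20. A second probe of ASS1 gave 1.81, and another stayed below background on all 3 arrays. SLC7A1, the main cationic amino acid transporter, differed by 0.94 and SLC7A2 by 0.72. In polyamine synthesis and breakdown, ODC1, ornithine decarboxylase, differed by 0.75, its antizyme gene OAZ2 by 0.81 and the spermidine acetyltransferase gene SAT1 by 0.72. OAT, ornithine aminotransferase, was at -0.76, the polyamine oxidase gene PAOX at -0.76 and ASL, which releases arginine from argininosuccinate, at -0.11. The transcripts of ARG1, ARG2, OTC, NOS1 and GATM were not above background on any array.

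Mitosis genes were lower under ADI-PEG20 as a group. All 37 members were below their untreated value, 20 of them at least 2-fold, with a median of -1.02 that lay below all random lists. Examples are the spindle gene DLGAP5 at -1.55, the kinase gene AURKA at -1.47 and the topoisomerase gene TOP2A at -1.36. MKI67, the proliferation marker Ki-67, was at least 2.503-fold lower. DNA replication genes had a median of -0.58 over 39 genes, with 36 lower and 3 at least 2-fold lower: POLA2, a subunit of DNA polymerase alpha, at -1.30, the replicative helicase subunit gene CDC45 at -1.23 and the ligase gene LIG1 at -1.09. DNA repair genes had a median of -0.34 over 24 genes, with BARD1 at -1.06 and EXO1 at -0.94, and a median of -0.19 without background correction. Replication-dependent histone genes had a median of -0.32 over 11 genes, at the 1.21st percentile, but of -0.05 with members at background included.

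Glycolysis genes had a median of -0.36 over 21 genes, 18 of them lower, at the 0.02nd percentile. PFKFB4, a regulator of phosphofructokinase, was at -1.26, the aldolase gene ALDOC at -1.20 and the mutase gene PGAM1 at -0.996. Hypoxia-induced genes, of which several also belong to glycolysis, had a median of -0.29 over 23 genes, with BNIP3 at -0.96 and, in the other direction, the MAX-binding repressor gene MXI1 at 0.97. Cholesterol synthesis genes had a median of -0.23 over 19 genes, at the 1.06th percentile, with ACAT2 at -1.08 and FDPS, farnesyl diphosphate synthase, at -0.99. Proteasome genes had a median of -0.20 over 27 genes, at the 0.39th percentile, with PSMD3 at -0.92.

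Several other groups were higher by less. Ribosome biogenesis genes had a median of 0.34 over 28 genes, 26 of them higher, with MYC at 1.05 and the nucleolar genes NOP58 at 0.85 and NOP16 at 0.84. FOXO and growth factor starvation genes had a median of 0.40 over 21 genes, or 0.23 with members below background on 1 array at their bound, and the thioredoxin-binding gene TXNIP was at 1.71. Targets of p53 had a median of 0.31 over 16 genes. Of these, SESN2, which is also in the ATF4 list, was at least 2.04-fold higher and GADD45A was at 0.96. Targets of NRF2, the factor of the antioxidant response, had a median of 0.27 over 17 genes. Of these, SLC7A11, which is also in the transporter list, was at least 2.22-fold higher and HMOX1, heme oxygenase, was at 1.12. Lysosome genes had a median of 0.17 over 34 genes, at the 99.8th percentile, with TPP1 at 0.82. Endoplasmic reticulum chaperone and unfolded protein response genes had a median of 0.19 over 19 genes, at the 98.0th percentile. In that list XBP1 was at 1.54, the chaperone gene HSPA5 at 0.99 and HYOU1 at 0.81, and no other member passed 1.5-fold. Cytosolic ribosomal protein genes had a median of 0.07 over 66 genes, at the 98.7th percentile.

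Median differences within the central 95% of random lists were found for autophagy genes, 0.09 over 33 genes, where GABARAPL1 was at 0.99 and MAP1LC3B at 0.65 but BNIP3 at -0.96 and BNIP3L at -0.60, and for mitochondrial biogenesis, 0.11. The same held for oxidative phosphorylation complex I, -0.07 over 33 genes, complexes II to V, -0.07 over 37, mitochondrial ribosomal proteins, -0.06 over 73, and the tricarboxylic acid cycle, -0.12 over 23, where IDH2 was at -1.20. It also held for fatty acid synthesis at 0.06, nucleotide synthesis at 0.08, translation factors at 0.07, heat shock proteins at -0.10, extracellular matrix and adhesion at -0.14, apoptosis regulators at -0.02 and interferon-stimulated genes at -0.03. Reference genes had a median of -0.08 over 16 genes, with PGK1, itself a glycolysis gene, at -0.82. Luminal markers had a median of -0.02 over 15 genes, with a sign that varied between settings from -0.17 to 0.07, and basal and mesenchymal markers -0.07 over 13. Markers of leukocytes were at -0.05 over 7 genes, of endothelium at -0.08 over 3 and of fibroblasts at 0.11 over 4, with a range over settings from -0.01.

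Among the remaining genes with the highest differences that were above background on both arrays, MKX, a homeobox gene, differed by 2.67, the calcium-binding protein gene S100P by 2.53 and PCK2, mitochondrial phosphoenolpyruvate carboxykinase, by 2.51. The untreated intensity of MKX was 174, near the background limit. The stress-induced regulator NUPR1 differed by 2.34, BEX2 by 2.25, the skin-associated gene DMKN by 2.06 (1.28 and 1.42 on other probes) and VLDLR-AS1 by 1.98. The cyclin gene CCND2 was at least 5.26-fold higher and the neuropeptide gene GAL at least 3.81-fold. At the other end, again above background on both arrays, was ASB9, which encodes a ubiquitin ligase adaptor, at -2.22 (-2.78 on another probe). Next were the spindle gene FAM83D at -2.03, CDCA2 at -1.88 and MAMDC2 at -1.88. TOGARAM2 was at -1.82, the ubiquitin ligase gene MARCHF4 at -1.78 and the sulfotransferase gene CHST4 at -1.76. The MAX partner gene MXD3 was at -1.71, RBM14 at -1.71 and TCF19 at -1.70 (-1.13 on another probe). SPOCD1 was at least 2.68-fold lower and CYB5RL at least 2.65-fold. The counts depend on the background correction, since without it 52 genes were 2-fold or more higher and 50 lower. Of the 195 and 235 genes, 111 and 165 were above background on both arrays.

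**Figure D1:**
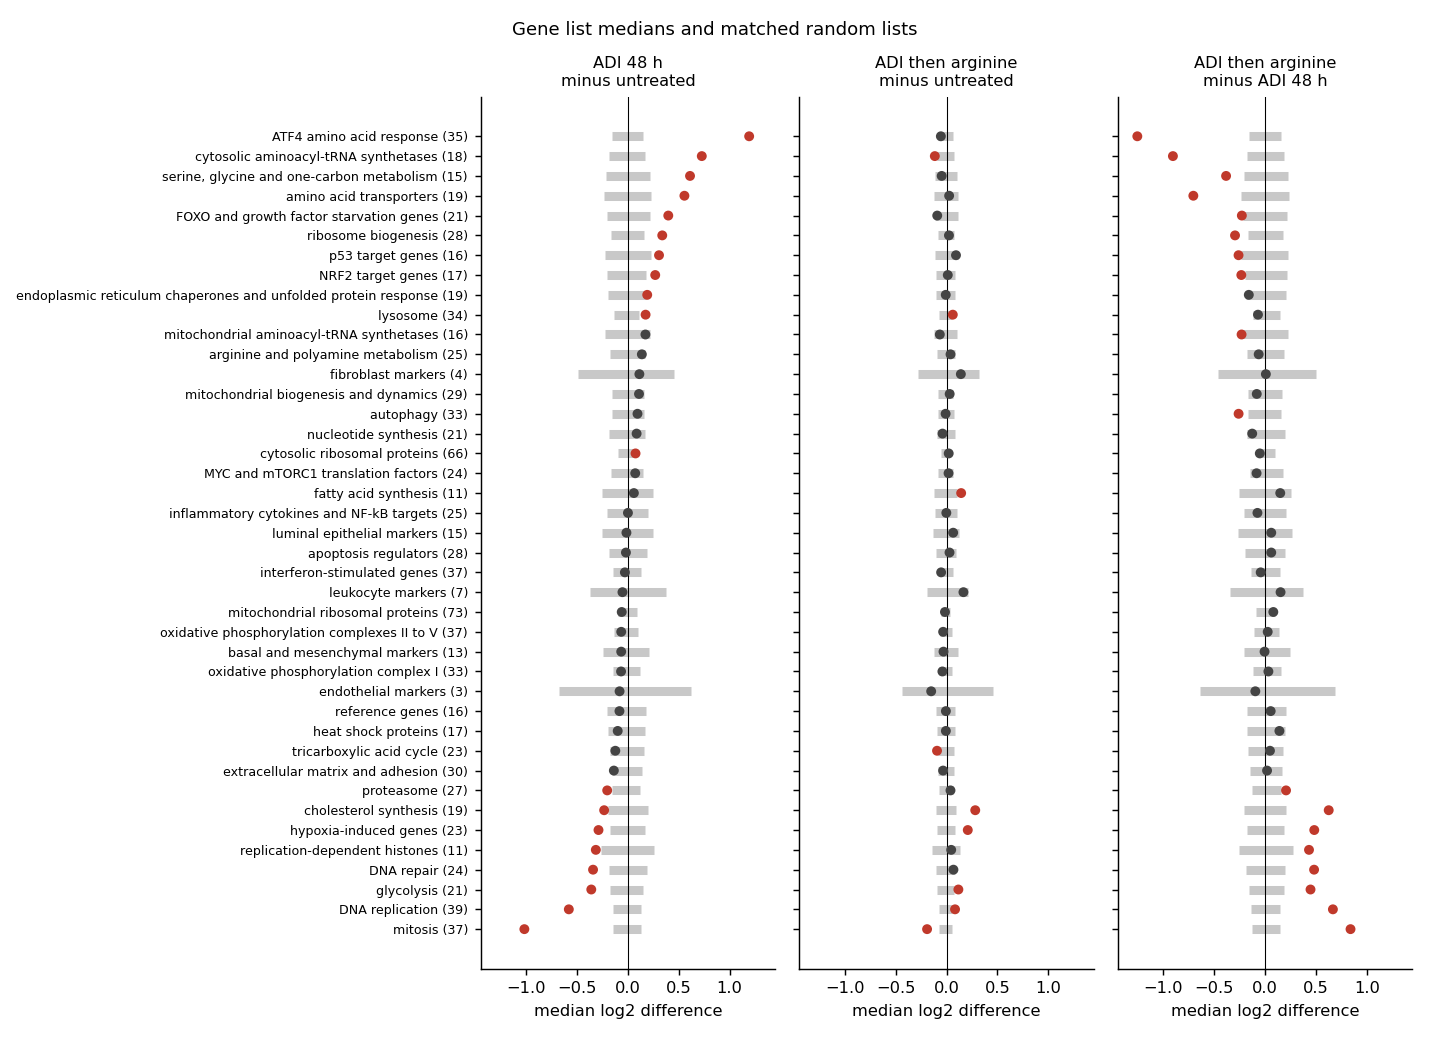
Median log2 difference of each gene list (points; number of genes above background in the first comparison in brackets) in the 3 comparisons, with the central 95% of 10000 expression-matched random lists as grey bars and medians outside it in red. ATF4 targets lie at 1.19 and mitosis genes at -1.02 in the left panel, and near 0 or at -0.19 in the middle panel.

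The second comparison asked whether cells returned to arginine for 24 h after 24 h of ADI-PEG20 differed from untreated cells. Few genes did by 2-fold or more. The median of ATF4 targets lay close to the untreated level, while some other groups that stood out under ADI-PEG20 lay outside the range of random lists. Among those groups, mitosis and lysosome genes lay on the same side as under ADI-PEG20. DNA replication, glycolysis, hypoxia-induced, cholesterol synthesis and cytosolic aminoacyl-tRNA synthetase genes lay on the opposite side. Of 11080 genes, the measured difference was 2-fold or more upward in 41 and downward in 37, or 3 and 1 with genes below background on 1 array at their bound, and the SD of the differences was 0.28, against 0.46 under ADI-PEG20. Simulated arrays with no change, with noise set from the probe error and background of these same arrays, were also counted. They had 48 genes past 2-fold upward and 45 downward, of 11474 genes. The measured counts were not above these, and the single genes named below are not set apart from noise by them. However, the SD of the simulated differences was 0.2896, above the measured 0.2808. Simulated counts as high as the measured ones were thus close to fixed in advance. The counts therefore cannot tell whether some of the measured differences are real. ASNS was at an intensity of 665 beside 664 in untreated cells. ATF4 targets had a median of -0.06 over 32 genes, at the 9.73rd percentile.

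Some groups lay outside the central 95% of random lists by small amounts. Mitosis genes had a median of -0.19, with 33 of 37 lower and none past 1.5-fold, and the largest were CENPF at -0.44, NEK2 at -0.43 and HMMR at -0.43. DNA replication genes were at 0.08 over 39 genes, with FEN1 at 0.43 and POLA2 at -0.51. Cytosolic aminoacyl-tRNA synthetases were at -0.12, with YARS1 at -0.39. Cholesterol synthesis genes were at 0.28 over 19 genes, 16 of them higher, with MVD, mevalonate diphosphate decarboxylase, at 0.86 and HMGCS1, hydroxymethylglutaryl-CoA synthase, at 0.67. Their regulator SREBF2 was at least 1.69-fold lower. Fatty acid synthesis genes were at 0.14 over 11 genes, with FADS2 at 0.36. Hypoxia-induced genes were at 0.21 over 23 genes, with EGLN1 at 0.52, and glycolysis genes at 0.12 over 21, with ENO2 at 0.41. Lysosome genes were at 0.06 and tricarboxylic acid cycle genes at -0.09, or -0.05 with the mean over each gene's probes.

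Among single genes above background on both arrays, the highest differences were those of GET3, of tail-anchored protein insertion, at 1.15, OAZ2 at 1.11, the AP-1 gene JUNB at 0.98 and ZNF426 at 0.97. NCMAP was at 0.95, TSPAN1 at 0.92, FCGR3B at 0.89, ZNF81 at 0.88, RNY1 at 0.86, F8A3 at 0.86 and the glycine cleavage gene AMT at 0.84. OAZ2 was also higher under ADI-PEG20, at 0.81, as was JUNB, at 1.07. The lowest among genes above background on both arrays were CREB3, a membrane-bound transcription factor gene, at -1.39 after arginine and -1.09 under ADI-PEG20, then RGMA at -0.98, LRRC8B at -0.90, RNF141 at -0.90, ZXDA at -0.90 and CHML at -0.88. ZNF121 was at -0.80, SEPTIN3 at -0.78, the autophagy gene GABARAP at -0.77, AFAP1L1 at -0.76, ZSCAN31 at -0.76 and NUDT8 at -0.75. TSPYL2, MIR25 and METTL16 were at least 2.01-fold, 1.89-fold and 1.76-fold higher. ZFP30, CYP4X1 and CFI were at least 1.96-fold, 1.88-fold and 1.77-fold lower. Other probes disagreed for F8A3, at -0.05, SEPTIN3, at 0.67, and TSPYL2, at -0.09, and the correlation between 2 probes of a gene was 0.206 over 2541 genes, against 0.724 under ADI-PEG20. Without background correction no gene was past 2-fold in either direction, and with genes above background on both arrays 2 were higher and 1 lower.

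The differences from the untreated array were then set beside each other for the 2 treated samples. Of the 195 genes with a measured difference of 2-fold or more upward under ADI-PEG20, 4 also measured that much higher after arginine, and of the 235 lower genes 14 measured that much lower. Above background on all 3 arrays were 0 of the 4 and 1 of the 14, and with dim values at their bound 1 gene stayed in each direction, TSPYL2 and CREB3, named after their values were seen. The median ratio of the difference after arginine to that under ADI-PEG20 was 0.0822 for the higher genes (interquartile range -0.0484 to 0.329) and 0.142 for the lower genes (-0.0052 to 0.352). A ratio of 0 is a full return to the untreated level and 1 a difference kept. Because both differences share the untreated array, simulated arrays with no change and equal noise gave 0.497, and the observed ratio was under 0.5 for 170 of the 195 and 197 of the 235 genes. No gene past 2-fold in one direction under ADI-PEG20 was past it in the other after arginine. This was largely given in advance by the shared untreated array and says little about the return. In simulated unchanged arrays with noise as large as all observed differences, 94.1% of genes past 2-fold had the same sign in both. Across 11448 genes, which are not independent replicates, the correlation of the differences was 0.275 and their covariance 0.0355. Simulated unchanged arrays of equal noise had a correlation of 0.498. Their covariance was 0.0169 for noise of 0.1303 per array, from the median absolute deviation form of the probe error. It was 0.0846 for noise as large as all observed differences. The untreated array could not be split, so part of the overlap may come from it.

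**Figure D2:**
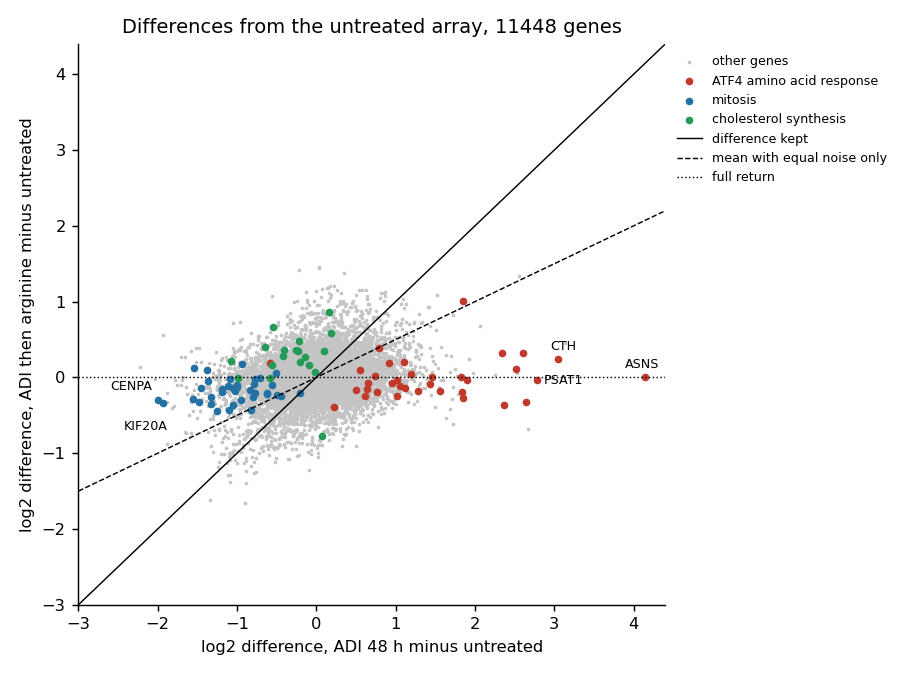
Log2 difference from untreated cells after ADI-PEG20 for 48 h (x axis) and after ADI-PEG20 then arginine (y axis), 1 point per gene above background on at least 1 of the 3 arrays. Lines mark a difference kept, the mean of simulated unchanged arrays of equal noise that share the untreated array, and a full return, and most ATF4 targets and mitosis genes lie near the last. The ATF4 target at 1.01 on the y axis is SESN2, which was below background in untreated cells.

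The third comparison set cells returned to arginine beside cells kept under ADI-PEG20 for the full 48 h. It was close to the mirror image of the first, with amino acid response transcripts lower and cell division transcripts higher after arginine. Among genes above background on both arrays, ASNS was at -4.14, PSAT1 at -2.82, CTH at -2.81, S100P at -2.48 and PCK2 at -2.41, with smaller differences of the same sign on other probes of PCK2. ASB9 was at 2.36 (2.70 on another probe), FAM83D at 2.01, MXD3 at 1.98, and STC1, the hormone stanniocalcin, at 1.92. Of 11129 genes, the measured difference was 2-fold or more upward after arginine in 227 and downward in 209, or 165 and 144 with genes below background on 1 array at their bound.

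ATF4 targets had a median of -1.26 over 35 genes, or -1.15 with members below background on 1 array at their bound, which leaves 21 at least 2-fold lower, and cytosolic aminoacyl-tRNA synthetases -0.91 over 18, with 9 at least 2-fold lower. Amino acid transporters were at -0.71 over 20 genes, serine, glycine and one-carbon genes at -0.38 over 15, ribosome biogenesis genes at -0.30 over 28, with MYC at -1.21, and autophagy genes at -0.26 over 34. The serine and one-carbon median was -0.21 with members at background included, and the ribosome biogenesis and autophagy medians were -0.18 and -0.17 without background correction. Mitosis genes were at 0.84, all 37 of them higher, with CENPA at 1.70 (1.13 on another probe), and MKI67 was at least 2.73-fold higher. DNA replication genes were at 0.67, with RRM2, a ribonucleotide reductase subunit, at 1.35, and DNA repair genes at 0.48, or 0.29 without background correction. Cholesterol synthesis genes were at 0.63, 18 of 19 higher and 11 past 1.5-fold, with ACAT2 at 1.29, HMGCS1 at 1.21 and INSIG1 at 1.06. Hypoxia-induced genes were at 0.48, with BNIP3 at 1.33 and ANKRD37 at 1.28, and glycolysis genes at 0.45, with PFKFB4 at 1.60, ALDOC at 1.42 and ENO2 at 1.26. ASS1 was at -1.02, SAT1 at -1.07, ODC1 at -1.03 and SLC7A1 at -0.90.

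Further genes lower after arginine were the cytokine gene IL24 at -2.34, PHGDH at -2.28, BEX2 at -2.21, the defensin gene DEFB103A at -2.16 (-0.97 on another probe), the stress cytokine gene GDF15 at -2.12, the tubulin gene TUBE1 at -2.10 and TRIB3 at -2.03. MKX, SLC6A9 and CCND2 were at least 8.004-fold, 6.001-fold and 5.26-fold lower. Further genes higher were DENND2A at 1.94, MARCHF4 at 1.74, the peroxisomal oxidase gene ACOX2 at 1.69 and CDCA2 at 1.67. CHST4 was at 1.66, TCF19 at 1.66 (1.30 on another probe) and the splicing gene SNRPA at 1.66. ARTN and LRRC45 were at least 3.29-fold and 2.98-fold higher. These 2 samples differ in the length of ADI-PEG20 exposure as well as in arginine, and the comparison shares the ADI-PEG20 array with the first, so the correlation of -0.817 between them stands beside -0.501 for simulated unchanged arrays of equal noise. Without background correction 48 genes were 2-fold or more higher and 58 lower.

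**Figure D3:**
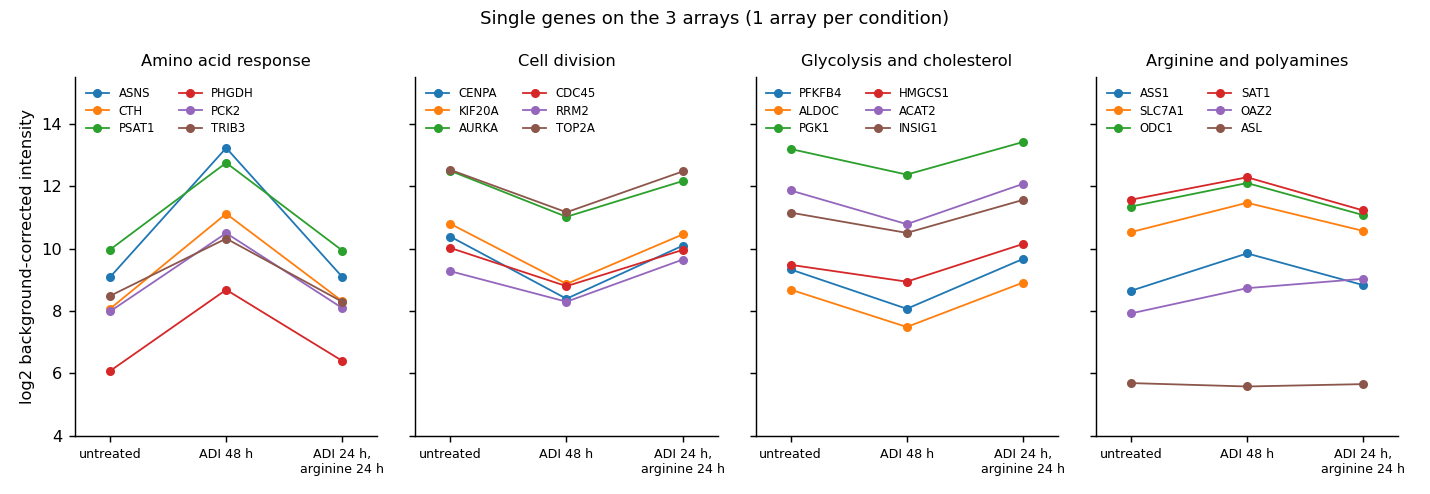
Log2 background-corrected intensity of single genes on the 3 arrays (x axis; 1 point per array, joined by gene, no replicates). Amino acid response genes and ASS1 were highest under ADI-PEG20, cell division, glycolysis and cholesterol synthesis genes were lowest there, and OAZ2 was highest after arginine.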

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

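Saddle-point normexp, a 0.99 normal quantile as background limit and bounds for genes above background on 1 of 2 arrays were added after seeing the data. Median scaling was void, since the columns share a distribution, the authors' values as deposited are the setting without background correction, detection p-values were replaced by background quantiles, and no array could be left out with 1 per condition. All 579 alternative values of named genes past 2-fold kept their sign, and 36 came under 2-fold, 23 of them without background correction. Most settings rescale or filter the same probe values, so a kept sign was largely fixed in advance and says little. Sizes did move. Without background correction 88 named gene values moved by at least the probe error of their comparison and 2 did not. These numbers were 62 and 28 with an offset of 50, and 53 and 37 with saddle-point normexp. The 46 list medians outside the central 95% of random lists kept their sign in all 414 alternative values. That too was in part fixed in advance, since mostly the same probe values enter. Some other medians crossed 0, such as those of luminal markers (-0.17 to 0.07), apoptosis regulators (-0.02 to 0.02) and fibroblast markers (-0.01 to 0.11) under ADI-PEG20. The median of ATF4 targets under ADI-PEG20 ranged from 0.88 to 1.19 and that of mitosis genes from -1.02 to -0.90. Of the 46, 12 moved by over 1.5 times in some setting. Without a background limit, the replication-dependent histone median under ADI-PEG20 went from -0.32 to -0.05, that of serine and one-carbon genes from 0.61 to 0.27 and that of FOXO genes from 0.40 to 0.23. The DNA repair median went from -0.34 to -0.19 without background correction.

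Counts past 2-fold depended on how dim probes were treated, since background correction stretches and an offset shrinks their differences. Genes higher and lower under ADI-PEG20 numbered 52 and 50 without background correction, 88 and 101 with an offset of 50, 120 and 138 with saddle-point normexp, 884 and 1034 at 1.5-fold, and 34 and 22 at 3-fold. Requiring both arrays above background left 111 higher, and bounds left 127. After arginine against untreated they were 0 and 0 without background correction, 1 and 1 with an offset of 50, 2 and 1 with both arrays above background, 3 and 1 with bounds, 6 and 11 with saddle-point normexp, 294 and 298 at 1.5-fold, and 0 and 2 at 3-fold. After arginine against ADI-PEG20 they were 48 and 58, 99 and 94, 129 and 121 with saddle-point normexp, 1100 and 992 at 1.5-fold, and 24 and 34 at 3-fold. Requiring both arrays above background left 133 lower there. The median ratio of the 2 differences for genes higher under ADI-PEG20 was -0.0265 without background correction, 0.0096 with an offset of 50, 0.0288 with both arrays above background, 0.0235 with saddle-point normexp and -0.0186 on a second probe. For lower genes it was 0.107 without background correction, 0.105 with both arrays above background and 0.0899 on a second probe. The ratio was not computed with bounds. The cause was not tested further.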

Other observations

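The list of inflammatory cytokines and NF-kB targets had a median of -0.0004 over 25 genes under ADI-PEG20, with 12 higher and 13 lower. Among its members, the collagenase gene MMP1 differed by 1.92, IL24 by 1.72, and the stromelysin gene MMP3 was at least 2.40-fold higher. After arginine MMP1 was at 0.25 and IL24 at -0.62 against untreated cells. In other lists, none of which stood apart as a whole, the epithelial cadherin gene CDH1 was at 1.03 but the luminal factor gene SPDEF at -1.002, the receptor gene EGFR was at 1.07 but the mesenchymal marker S100A4 at -0.64, and the death receptor gene TNFRSF10A was at 1.18. The survivin gene BIRC5, which also serves in mitosis, was at -1.38, and IFIT1, an interferon-induced gene, at -1.13. These genes were chosen after their values were seen.

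Cholesterol synthesis genes were the group farthest above untreated cells after arginine, with a median of 0.28, although they were at -0.23 under ADI-PEG20. On other probes of 6 of these genes the median after arginine was 0.26, with a bootstrap interval over genes of 0.02 to 0.66. The lower end missed the limit set before, so this test could not tell whether errors of single probes account for the difference. Mitosis genes stayed at -0.19 after arginine while DNA replication genes were at 0.08. On other probes the mitosis median was -0.19 and the replication median 0.02, a difference of -0.21 with an interval of -0.42 to 0.05 that includes 0.

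Of the tests in the following paragraphs, those on other probes of the ATF4 and mitosis lists, on random lists, on chaperones, on a second probe of the genes past 2-fold and on noise were set after the results they bear on had been seen at least in part. The tests on other probes after arginine, given above, and the count of ADI-PEG20 samples were set before.

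ATF4 targets were higher under ADI-PEG20. Errors of single probes are argued against by other probes of 7 of these genes, which had a median of 1.25 (bootstrap interval 0.75 to 2.74). A bias that follows intensity is argued against by random lists of matched expression, since the list's median was at percentile 100. The chaperone list does not settle whether a general endoplasmic reticulum stress took part. Its median of 0.19 (interval -0.11 to 0.30) was below that of ATF4 targets but at the 98.0th percentile of random lists. In it XBP1 was at 1.54 and HSPA5 at 0.99, and the test compared the sizes of unlike gene sets. A response of the ATF4 pathway to arginine shortage may account for the pattern, as a hypothesis from 1 array that no replicate has tested.

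Mitosis genes were lower under ADI-PEG20. On other probes of 17 of these genes the median was -1.06 (interval -1.41 to -0.78) and all 17 were lower, which argues against errors of single probes. Random lists of matched expression, among which the median was at percentile 0.0, argue against a bias that follows intensity. A lower share of dividing cells under ADI-PEG20 could give such a pattern, as could a lower level in each cell, and the arrays hold no count of cells in each phase.

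The differences under ADI-PEG20 were mostly absent after arginine. Noise of equal size in the 3 arrays would give a ratio near 0.497, and the larger of the observed ratios was 0.142 (bootstrap interval 0.111 to 0.176). A noisier ADI-PEG20 array would give a lower ratio, which this test leaves open. Choice of noisy probes is argued against by a second probe of the same genes, which held at least 0.746 of the first probe's difference, with 42 of 45 higher and 48 of 53 lower genes of the same sign. Restored arginine, a shorter ADI-PEG20 exposure and an ADI-PEG20 sample that stands apart for another reason, such as density or RNA handling, cannot be told apart with 1 ADI-PEG20 sample of 48 h.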
